A study of Mus musculus with 24 samples.

How the data were processed

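The study profiled RNA of the developing lens of C57BL/6 mice at embryonic days 15 and 18 (E15, E18) and postnatal days 0, 3, 6 and 9 (P0, P3, P6, P9). At each of the 6 stages 2 biological replicates were collected, A and B, each a pool of lenses from 8 to 9 pups. Per the labels, lenses were dissected with forceps under a microscope, RNA was extracted with Trizol, and each pool gave an mRNA library (TruSeq RNA v2) and a small-RNA library (TruSeq Small RNA), sequenced on a HiSeq2000. This makes 24 libraries in 12 groups of 2. The pools are separate animals, so the tests measure the spread between pools. With 2 pools per stage, that spread was estimated over all stages together.

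The authors deposited 1 table per library. Each mRNA table holds 30705 genes by symbol with a UCSC transcript identifier, and each small-RNA table holds 1908 mature miRNAs. The unit of the deposited mRNA values is not given in the sources used here and was read from the values as RPKM: low values of a gene are whole multiples of a step that is inversely proportional to its transcript length. Within 0.1 read, 89.2% to 92.3% of the low values tested per library were whole, where chance gives 20%. The step gives an estimated depth, in units of 1e6 assigned reads, of 20.4 (P9 B) to 44.0 (E18 B). The deposited miRNA values are an unnamed signal that the authors scaled, since each column sums to between 0.764 and 0.817 (in units of 1e6). The step was tested in the mRNA values only, so the depth of the small-RNA libraries was not estimated and is unknown. Per the submitters' processing notes, Bowtie 0.12.8, SAMtools 0.1.18 and the mouse build GRCm38/mm10 were used; their roles and the counting of reads on several genes or loci are not given in the sources used here. A gene at 1 RPKM with a 2 kb transcript rests on 40.8 reads in the shallowest library and 88.0 in the deepest, so levels well below 1 RPKM carry large counting error. In every mRNA library values worth 2 reads outnumbered values worth 1 read, by 1.26 (E18 B) to 1.71 times (E15 B). Reads may thus have been counted in pairs, which would leave fewer independent fragments behind a value than these reads. Read counts were not used here, and no count-based test was run.

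Because RPKM and the miRNA signal are relative to the total of a library, a rise of a few very abundant RNAs lowers every other value. The 16 crystallin genes took 33.0% of summed RPKM at E15 and 61.0% at P9. Each comparison was therefore repeated after median-ratio rescaling (each library divided by the median ratio of its values to the geometric means of the features) and after quantile normalization, and levels and calls are on the deposited scale unless another scale is named. Reads of near-identical copies (gamma crystallins, the alpha and beta globin genes, ribosomal protein genes and their pseudogenes, Gapdh) can be placed on the wrong copy, and 89 miRNAs had 12 values equal to those of another miRNA; single members of these groups are uncertain.

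Features with a value of at least 1 in at least 2 libraries were tested: 14405 genes and 777 miRNAs. Values were taken as log2(value + 1), so fold changes are on the log2(value + 1) scale and understate changes of low genes. One limma model (version 3.58.1 in R 4.3.3) per assay, with stage as a factor of 6 levels over all 12 libraries and 6 residual degrees of freedom, gave moderated tests with an intensity trend, adjusted by the Benjamini-Hochberg method; a feature is called at an adjusted p below 0.05. The comparisons were all stages jointly, P9 against E15, the mean of the postnatal stages against the mean of the embryonic stages, and each pair of consecutive stages. Fold changes are given with their standard errors, levels as mean ± SD over the 2 pools of a stage. Tables were read with Python 3.11.15 and pandas 2.3.3; numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining tests and the plots.

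The procedure was tested on simulated data drawn from each feature's own mean and residual spread, with changes added at P9 to features of more than low abundance. Among 14405 genes, 74.7% of 91 genes changed by 1 on the log2 scale and 98.2% of 109 genes changed by 2 were recovered, with 5.41% of calls false. Among 777 miRNAs the corresponding shares were 76.0% of 96 and 96.2% of 104, with 3.35% of calls false. Simulated features varied independently and with the same spread at every stage. In the real data the E15 mRNA pools differed more than the others and many genes moved together. These shares may therefore not hold for comparisons with E15.

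Chosen before the data were examined were the test, the comparisons, 29 gene lists and 12 miRNA lists, and the rule for naming genes. The rule takes up to 4 called members with the largest change of each list, or the most abundant member as a value where none was called; the 6 largest rises and falls in P9 against E15 and postnatal against embryonic, or 3 each way in consecutive pairs, among features above the median abundance whose pools did not overlap; 9 lens and proliferation genes, miR-184, miR-204 and the let-7 total at each stage; and the 5 most abundant features per assay. The text gives a selection of these; some results are not reported here. The gene lists are crystallins, fiber cell membrane and cytoskeleton, lens epithelium, lens transcription factors, non-crystallin cataract genes, cell cycle, CDK inhibitors, autophagy and mitophagy, glutathione and antioxidant, glycolysis, cholesterol synthesis, lens capsule and basement membrane, FGF signalling, Notch signalling, ion and water transport, heat shock and chaperones, ribosomal proteins, mitochondrially encoded genes, immediate early and stress genes, interferon response, markers of erythroid cells, endothelium, pericytes and smooth muscle, macrophages, photoreceptors and retina, pigment cells, cornea and surface epithelium, and mesenchyme and fibroblasts, and transcripts of the sex chromosomes. The miRNA lists are the let-7 family, lens-reported miRNAs, miR-17-92 and paralogues, the miR-200 family, the miR-183 cluster (with miR-96 and miR-182), the Dlk1-Dio3 cluster, the miR-30 family, the miR-29 family, and erythroid, endothelial and blood, neural, and muscle and mural miRNAs. Lists share some members; Mip, for example, stands in 3 of them.

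Lists were compared with all other tested features by limma's camera with a preset correlation of 0.01, adjusted over the lists of an assay, and again with an estimated correlation. Each list count is also given adjusted over the list alone where that count differs. Other settings fixed beforehand were the rescalings above, limma without trend, no filter, a stricter filter (at least 10 in at least 2 libraries), a pseudocount of 0.1, an absolute log2 fold change of at least 1, the replicate letter as a block, a fit with only the libraries of the 2 stages, leaving out each library, and a detection level of 10. Added after the data were seen was the non-crystallin scale, each library divided by its share of summed RPKM not taken by crystallins. It does not equalize summed RPKM itself, which ran from 438777 (E15 A) to 636619 (P9 A). Also added were a covariate of retinal marker level (log2 of Rax), a fit without P3, and the lists without each library. Rax is confounded with stage, so calls lost with that covariate can reflect wider standard errors. Correlations over the 6 stages were tested by exact permutation. Seed sites were sought in 3' UTRs of at least 50 bases and compared within 10 strata of UTR length by 100000 permutations and against 200 shuffled sites, and 100 splits of the 12 libraries into 8 and 4 and, added later, the 15 splits of whole stages into 4 and 2 were refitted. Coordinates are 1-based positions in GRCm38 from the reference annotation.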

Results

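Crystallin transcripts, which encode the structural proteins of the lens, filled a growing part of the mRNA libraries. The 16 crystallin genes held 33.0% ± 7.82 of the authors' summed RPKM at E15 (mean ± SD, 2 pools per stage), 34.1% ± 0.644 at E18, 51.5% ± 0.947 at P0, 51.7% ± 0.294 at P3, 59.1% ± 0.839 at P6 and 61.0% ± 0.460 at P9. Over the 12 mRNA libraries the most abundant transcripts were Cryba1 (mean 41502.8 RPKM, 7.60% of the sum), Cryaa (6.91%), Cryga (4.49%), Cryge (3.55%) and Crygb (3.45%), the gamma crystallins being uncertain singly because they share reads. Among miRNAs, miR-184-3p (mean signal 87087.3, 10.8% of the sum) and miR-204-5p (9.54%) led, followed by miR-181a-5p (7.26%), miR-182-5p (6.26%) and miR-92a-3p (4.25%). A mean of 12821.5 ± 666 genes reached 1 RPKM per library (12010 in P6 B to 13962 in E18 B), and 661.75 ± 37.2 miRNAs reached a deposited signal of 1 (612 in P9 A to 730 in E15 B).

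The 2 E15 mRNA pools differed more than those of any other stage. Crystallins took 27.5% of RPKM in E15 A and 38.5% in E15 B, and the retinal transcription factor gene Rax (75.6 and 20.2 RPKM) differed the other way. The median absolute log2 difference between pools was 0.35 at E15 and 0.11 to 0.15 at the other stages, and the variance between pools was 188 times counting noise at E15 against 11.8 to 17.2 times elsewhere. That noise was computed with each read taken as independent. In the small-RNA libraries P3 stood out, with a median difference of 0.51 against 0.19 to 0.32. The model takes the same spread at all stages, which these values go against. Pairs without the wide stage (E15 for mRNAs, P3 for miRNAs) thus tend to get standard errors that are too wide, and pairs with it too narrow. On the first principal component of the tested genes (70.0% of variance) E15 A lay at -82.0 and E15 B at -34.9. The second miRNA component (14.8% of variance, after 61.3% for the first) put P3 A at -21.0 and P3 B at -6.77.

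Lens genes followed separate courses over the 6 stages. Crybb2, a beta crystallin (chromosome 5, 113058258-113070117, GRCm38), went from 18.9 ± 0.538 RPKM at E15 through 129.6 ± 6.37, 2467 ± 10.1, 7040.19 ± 39.2 and 14018 ± 107 to 21179 ± 992 at P9. Crygs (chromosome 16, 22805203-22811410) rose from 364 ± 164 to 16869.5 ± 1309, and the small heat shock protein gene Cryab from 1125 ± 367 to 11183 ± 201. Cryaa (chromosome 17, 31677931-31681730) stood at 27562 ± 6810 at E15, 41176 ± 1966 at P0 and 44904 ± 124 at P9. Mip, the fiber cell water channel, measured 2146 ± 957 at E15, 1462 ± 29.6 at E18, 3356 ± 301 at P0 and 3774 ± 137 at P9. Pax6, which specifies eye tissue including retina (chromosome 2, 105668896-105698410), was highest at E18 (258 ± 8.59) and stood at 93.6 ± 4.27 at P9. Foxe3, a factor of the lens epithelium, was at 69.2 ± 30.9 at E15, 17.6 ± 1.31 at E18 and 35.1 ± 1.96 at P9. Prox1, which drives fiber elongation, went from 31.1 ± 3.36 at E18 to 89.3 ± 0.986 at P0, and the proliferation gene Mki67 from 32.0 ± 0.879 to 8.65 ± 0.539 and on to 2.87 ± 0.274 at P9. Deposited miR-184-3p signal was 56273 ± 6443 at E15 and 124177 ± 19479 at P9, miR-204-5p 74196 ± 1520 and 79281 ± 8315, and the let-7 total 17143 ± 3011 and 24051 ± 4.57. The courses between were not steady, with swings at P3, where the small-RNA pools differed most. From P0 through P3 to P6 miR-184-3p went from 102489 ± 2532 to 55098 ± 12505 and 123472 ± 5468. The let-7 total went from 18223 ± 769 to 32116 ± 8611 and 19886 ± 292. Across the 6 stages 10687 of 14405 genes and 502 of 777 miRNAs changed (limma, joint test of stage), against 6847 and 441 after median-ratio rescaling and 7040 and 409 after quantile normalization.

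**Figure D1:**
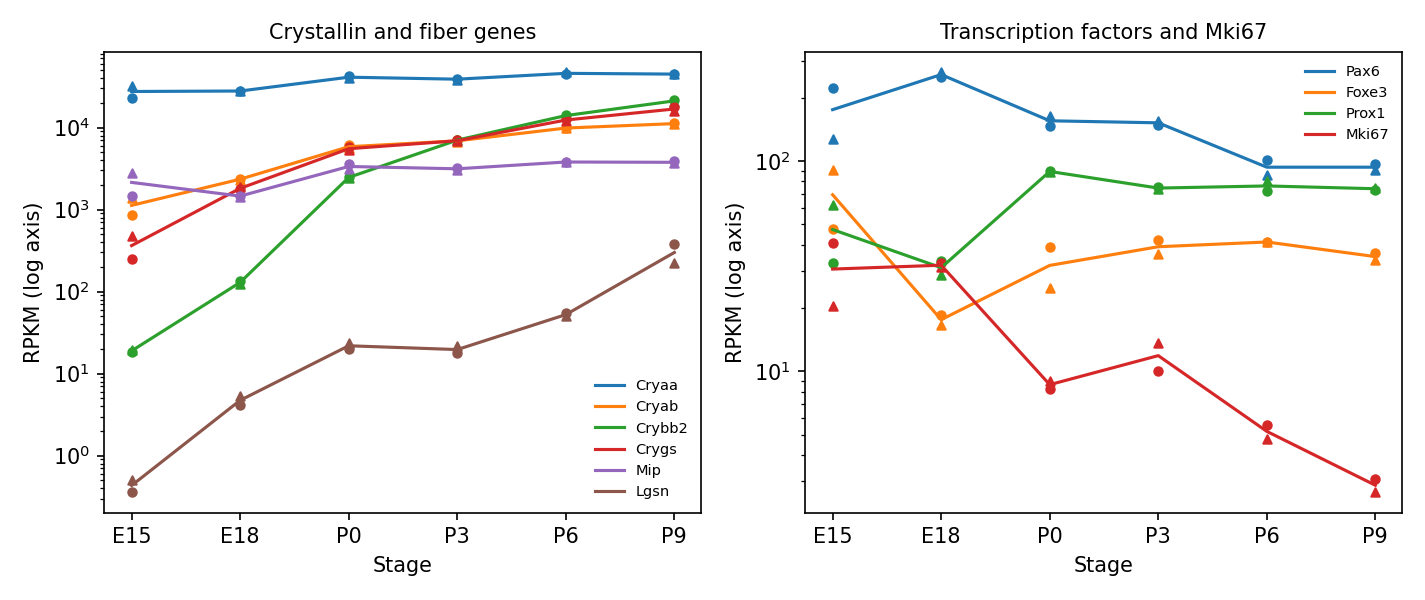
RPKM (log scale) of crystallin and fiber genes (left) and of lens transcription factors with Mki67 (right) at each stage; circles are replicate A, triangles replicate B, and lines join the means of the 2 pools. Crybb2 rises at every step from 18.9 to 21179 RPKM, while Mki67 falls from 32.0 at E18 to 2.87 at P9.

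Between E15 and P9 the transcripts of fiber cell differentiation rose. Of 16 crystallins 15 rose, none fell and 1 did not pass, with a median log2 fold change of 1.22, which is 1.76 above the median of all genes. Largest were Crybb2 (10.05 ± 0.10, SE; adjusted p = 8.7e-13), Crygs (5.61 ± 0.24), Cryab (3.35 ± 0.19) and Crygb (2.45 ± 0.24, 6377 ± 2611 to 33344 ± 1977 RPKM). Among 18 genes of the fiber membrane and cytoskeleton 15 rose, 1 fell and 2 did not pass. Lgsn, a lens glutamine synthetase-like gene (chromosome 1, 31176281-31204725), rose from 0.432 ± 0.0969 to 300.2 ± 113 RPKM (7.67 ± 0.22; adjusted p = 8.6e-09). Lctl went from 10.7 ± 4.12 to 611 ± 60.4, Birc7 from 22.4 ± 11.2 to 391 ± 38.1, and Dnase2b, the nuclease that clears fiber cell nuclei, from 8.67 ± 5.17 to 92.0 ± 12.1. With Rax as a covariate 7 of the 16 crystallins rose and 9 did not pass, and of the 18 fiber genes 9 rose, 2 fell and 7 did not pass.

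Capsule and transport genes moved the same way. Of 18 capsule and basement membrane genes 10 rose, 3 fell and 5 did not pass. The collagen IV chains Col4a3 (0.268 ± 0.0636 to 56.9 ± 4.17 RPKM; 5.51 ± 0.12) and Col4a4 (0.101 ± 0.0601 to 47.5 ± 2.45; 5.46 ± 0.11), neighbours on chromosome 1, rose most. Col4a2 rose by 1.76 and fibronectin Fn1 fell from 24.1 ± 8.99 to 2.14 ± 1.10. Ion and water transport had 8 of 11 genes rising and 3 not passing, 10 rising when adjusted over the list alone, among them Aqp5 (0.117 to 6.49 ± 0.211), Atp1b1 (log2 1.80) and Aqp1 (1.47). The Rax covariate left 8 capsule genes rising and 1 falling, and 7 transport genes rising. Of 23 non-crystallin cataract genes 10 rose, 4 fell and 9 did not pass; the beaded filament genes Bfsp1 (549 ± 318 to 3525 ± 187; 2.81 ± 0.30) and Bfsp2 (1219 ± 514 to 4093 ± 178; 1.81) and the membrane protein gene Lim2 (1.24) rose. Under the same covariate 5 cataract genes rose and 6 fell.

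Lens epithelium and transcription factor genes moved both ways, and their balance depended on the scale. In the epithelium list 2 of 12 rose, 3 fell and 7 did not pass on the deposited scale, against 7 rising and 0 falling after median-ratio rescaling (median 0.03 and 0.67). Npnt (11.3 ± 2.72 to 32.1 ± 1.55 RPKM; 1.44) and Dkk3 (556 ± 75.8 to 1337 ± 4.24; 1.27) rose on either scale. Foxe3 fell by 0.89 ± 0.27 (adjusted p = 0.0145; 0.0939 without E15 B and 0.0657 without P9 B) and was not called after median-ratio rescaling (-0.23). Pax6 fell by 0.85 ± 0.20 (176 ± 67.6 to 93.6 ± 4.27) on the deposited scale and was not called after median-ratio rescaling (-0.18). Of 18 lens transcription factors 3 rose, 6 fell and 9 did not pass (median -0.21), while 7 rose and 1 fell after median-ratio rescaling (median 0.33); Hsf4, a regulator of fiber genes, rose from 63.9 ± 34.0 to 187 ± 1.73 and Meis1 fell from 25.1 ± 15.5 to 6.84 ± 0.0983.

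Proliferation transcripts fell. All 30 cell cycle genes fell, on the deposited and the median-ratio scale alike, with a median of -2.97, or -2.43 relative to all genes. The ubiquitin-conjugating enzyme gene Ube2c (80.2 ± 26.4 to 3.48 ± 1.02 RPKM; -4.16 ± 0.30), Cdc20 (-3.52), topoisomerase Top2a (103 ± 47.4 to 7.60 ± 0.859; -3.52 ± 0.26) and Birc5 (-3.42) fell most. Among 7 CDK inhibitors 5 fell, 0 rose and 2 did not pass (6 fell adjusted over the list alone), Cdkn2d from 18.1 ± 0.484 to 5.31 ± 0.240 and Cdkn2a by 1.68. Notch signalling had 7 of 10 genes falling and 3 not passing; the Notch targets and receptors Hes5 (24.3 ± 17.9 to 3.60 ± 2.27), Notch1 (-1.47) and Notch3 (-1.37) fell. All 30 cell cycle genes were higher in E15 A than in E15 B (median log2 0.86), Mki67 at 40.8 and 20.6 RPKM, beside Hes5, Notch1 and Rax (75.6 and 20.2). With Rax as a covariate 29 of the 30 cell cycle genes fell and 1 did not pass, and of 10 Notch genes 3 fell, 1 rose and 6 did not pass.

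Housekeeping pathways mostly fell with the bulk of the genes. Of 19 cholesterol synthesis genes 18 fell and 1 did not pass (median -1.12, -0.58 relative to all genes; 10 fell after median-ratio rescaling): Nsdhl, a sterol dehydrogenase gene, went from 23.2 ± 1.43 to 6.43 ± 0.654 RPKM (-1.71 ± 0.13). Given the Rax covariate 12 cholesterol, 54 ribosomal, 8 glycolytic, 2 immediate early and 4 FGF genes fell, and 2 glycolytic and 2 FGF genes rose. Ribosomal protein genes, which share reads with pseudogenes, fell in 65 of 76 and did not pass in 11 (66 fell adjusted over the list alone), but 12 fell after median-ratio rescaling; Rps4x (97.4 ± 7.41 to 34.8 ± 7.22) and Rpl27a (-1.38) fell most. In glycolysis 14 of 18 fell, 2 rose and 2 did not pass, yet after median-ratio rescaling 1 fell and 2 rose. Aldoc, an aldolase, rose from 18.9 ± 7.97 to 374 ± 7.72 (4.30 ± 0.20), while Ldha fell from 143 ± 1.83 to 69.5 ± 11.6. Immediate early genes fell in 7 of 10, rose in 0 and did not pass in 3 (4 fell and 1 rose after median-ratio rescaling), Ier2 by 1.98 and Fos by 1.34. FGF signalling had 3 of 13 rising, 8 falling and 2 not passing (median -0.55), and a median of 0.09 after median-ratio rescaling; Etv4 (-1.81) and Dusp6 (-1.63), both FGF-induced, fell and Fgf1 (1.64) and Fgfr3 (1.09) rose.

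Stress and clearance genes held some of the largest single rises. Hmox1, heme oxygenase 1, rose from 24.1 ± 5.75 to 569 ± 44.2 RPKM (4.52 ± 0.14) and Gstm1 by 1.63, whereas the thioredoxin genes Txnrd1 (-1.69) and Txn1 (164 ± 10.9 to 52.6 ± 0.930) fell. In that antioxidant list 4 of 22 rose, 10 fell and 8 did not pass, 4 and 11 adjusted over the list alone, and its median of -0.39 became 0.24 after median-ratio rescaling, with 7 rising and 4 falling. Hspb1, a small heat shock protein gene, rose from 0.965 ± 0.261 to 148 ± 3.70 (6.25 ± 0.22). Heat shock and chaperone genes counted 4 of 15 rising, 10 falling and 1 not passing (median -0.59, and 0.08 after median-ratio rescaling), Hsph1 falling by 1.42 and Hspb2 rising by 1.78. Of 19 autophagy and mitophagy genes 4 rose, 5 fell and 10 did not pass (median -0.15, and 0.47 after median-ratio rescaling, with 10 rising and 1 falling). Alox15, a lipoxygenase, rose by 3.78, Gabarapl1 from 57.2 ± 17.5 to 160.4 ± 17.9, and Atg5 fell from 13.3 ± 1.08 to 4.79 ± 0.747. Interferon response genes rose in 3 of 8 and did not pass in 5, with Rsad2 at 2.13 and Mx1 at 0.95.

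Among abundant genes outside the lists, the fatty acid carrier Fabp5 (57.3 ± 8.31 to 3079 ± 205 RPKM; 5.73 ± 0.11) rose and the steroid reductase gene Srd5a2 was listed at 0 at E15 and measured 59.2 ± 1.07 at P9. The imprinted RNA H19 (chromosome 7, 142575530-142578146) fell from 1052 ± 290 to 6.37 ± 1.89 (-7.15 ± 0.19; adjusted p = 5.2e-09) and the neighbouring growth factor gene Igf2 from 206 ± 58.7 to 5.55 ± 0.941. Sfrp2 (158 ± 118 to 0.320; -6.69 ± 0.40) and Fgf15 (201 ± 178 to 1.42; -6.03 ± 0.53) also fell. Fgf15 measured 328 in E15 A and 75.1 in E15 B, differing between these pools the same way as Rax.

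Markers of cells outside the lens changed strongly as well. All 8 erythroid genes fell: the embryonic globin Hbb-y from 289 ± 5.91 RPKM to nearly 0 (-8.13), and the adult globins Hba-a2 (2809.7 ± 382 to 71.9 ± 25.8) and Hbb-b1 (1422 ± 28.6 to 35.4 ± 9.35), whose copies share reads. All 11 macrophage genes fell, with Lyz2 (18.2 ± 1.82 to 1.23 ± 0.427; -3.12), C1qc (-2.68) and Tyrobp (-2.67). Endothelial markers fell in 8 of 10 (9 adjusted over the list alone) and did not pass in 2, led by Tie1 (-2.12), Emcn (-2.09) and Pecam1 (-2.06). Of 5 corneal genes 4 fell (Krt5 -3.03, Krt15 -2.90) and 1 did not pass, and all 6 mesenchymal genes fell (Col1a1 -2.33). Pericyte and smooth muscle genes fell in 4 of 7, rose in 1 and did not pass in 2, the riser being actin Acta2 (5.77 ± 0.264 to 44.2 ± 1.92). All 8 erythroid, 5 of 11 macrophage, 6 of 10 endothelial, 4 of 5 corneal, 5 of 6 mesenchymal and 3 of 7 pericyte genes fell with Rax as a covariate.

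Photoreceptor transcripts rose, with large spread at P9. Of 13 photoreceptor and retina genes 8 rose, 3 fell and 2 did not pass (8 and 4 adjusted over the list alone). With Rax, itself a member, as a covariate 10 rose, 1 fell and 2 did not pass. Rod arrestin Sag went from 0.318 ± 0.165 to 70.8 ± 42.0 RPKM (5.64 ± 0.38), and Nrl (0.176 to 30.8 ± 16.9), Prph2 (log2 4.49) and Pde6b (4.07) rose with it; Sag measured 41.1 in P9 A and 100.5 in P9 B. Pigment genes rose in 1 of 6, fell in 2 and did not pass in 3 (median -0.13, and 0.28 after median-ratio rescaling): Tyrp1 rose by 1.12 and Mlana fell by 1.43. Of 5 sex-chromosome transcripts 1 rose, 3 fell and 1 did not pass, with Xist at 15.6 and 55.4 (adjusted p = 0.0091; 0.0581 without E15 A and 0.0562 without P9 B) and Kdm5d at 8.92 and 2.80. The sex-chromosome list holds female and male transcripts, and the sex of the pups in each pool was not available to the fit. A different mix of sexes between the pools and a change with stage therefore cannot be told apart for that list. Mitochondrially encoded genes were absent from the deposited tables (0 measured).

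**Figure D2:**
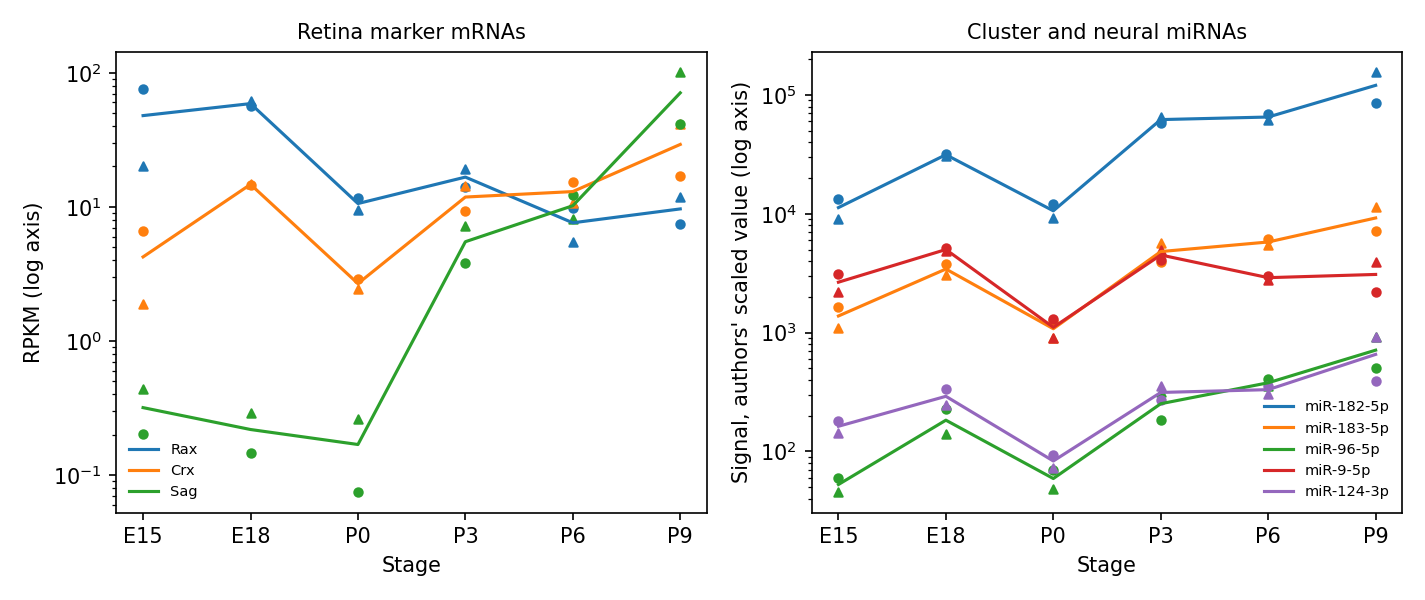
Retinal marker mRNAs (left, RPKM) and miRNAs of the miR-183 cluster and of neural cells (right, deposited signal) at each stage on log scales; circles are replicate A, triangles replicate B, lines the means. Rax separates the 2 pools at E15 (75.6 and 20.2 RPKM), Sag climbs from 0.169 RPKM at P0 to 70.8 at P9, and miR-182-5p drops from 31448 at E18 to 10602 at P0 before reaching 120607.

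In all, 9229 of 14405 genes changed between E15 and P9 (limma), 1246 up and 7983 down. The median log2 fold change of all genes was -0.54, and -0.01 after median-ratio rescaling, under which 3075 rose and 2822 fell; quantile normalization gave 2944 and 3200. Of 108 named calls 6 were lost without 1 library, among them Foxe3 and Xist, and 8 after median-ratio rescaling. Camera placed 16 lists apart from the other genes: upward crystallins (adjusted p = 1.25e-18), fiber (1.70e-16), capsule (1.07e-10), ion and water transport (1.07e-10), photoreceptor and retina (6.63e-08), cataract (2.00e-06), interferon (0.000925), epithelium (0.0110) and autophagy (0.0125); downward cell cycle (1.07e-10), erythroid (4.66e-06), ribosomal (2.08e-05), cholesterol (0.000481), macrophage (0.0185), cornea (0.0335) and endothelium (0.0369). Only ion and water transport stayed with an estimated correlation (adjusted p = 0.0114); the other 15 did not, among them crystallins (adjusted p = 0.163 with an estimated correlation), fiber (0.184), capsule (0.0839), cell cycle (0.345), erythroid (0.162) and ribosomal genes (0.434).

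Not set apart by camera were transcription factors (adjusted p = 0.0783), mesenchyme (0.178), CDK inhibitors (0.187), antioxidant (0.308), pigment (0.355), immediate early (0.566), FGF, Notch and heat shock (0.695 each), pericyte (0.699), glycolysis (0.712) and sex-chromosome transcripts (0.828). Because camera compares with the other genes, its direction was up while the median was below 0 for autophagy, transcription factors, antioxidant, FGF, heat shock, pericyte, pigment and sex-chromosome lists. Limma's fry, which asks whether a list moves one way without comparing it to other genes, gave adjusted p = 4.46e-05 for crystallins and 9.45e-05 for the cell cycle; its mixed form, open to either direction, gave an adjusted p of 2.42e-07 for the lens epithelium against 0.0723 one-way.

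**Figure D3:**
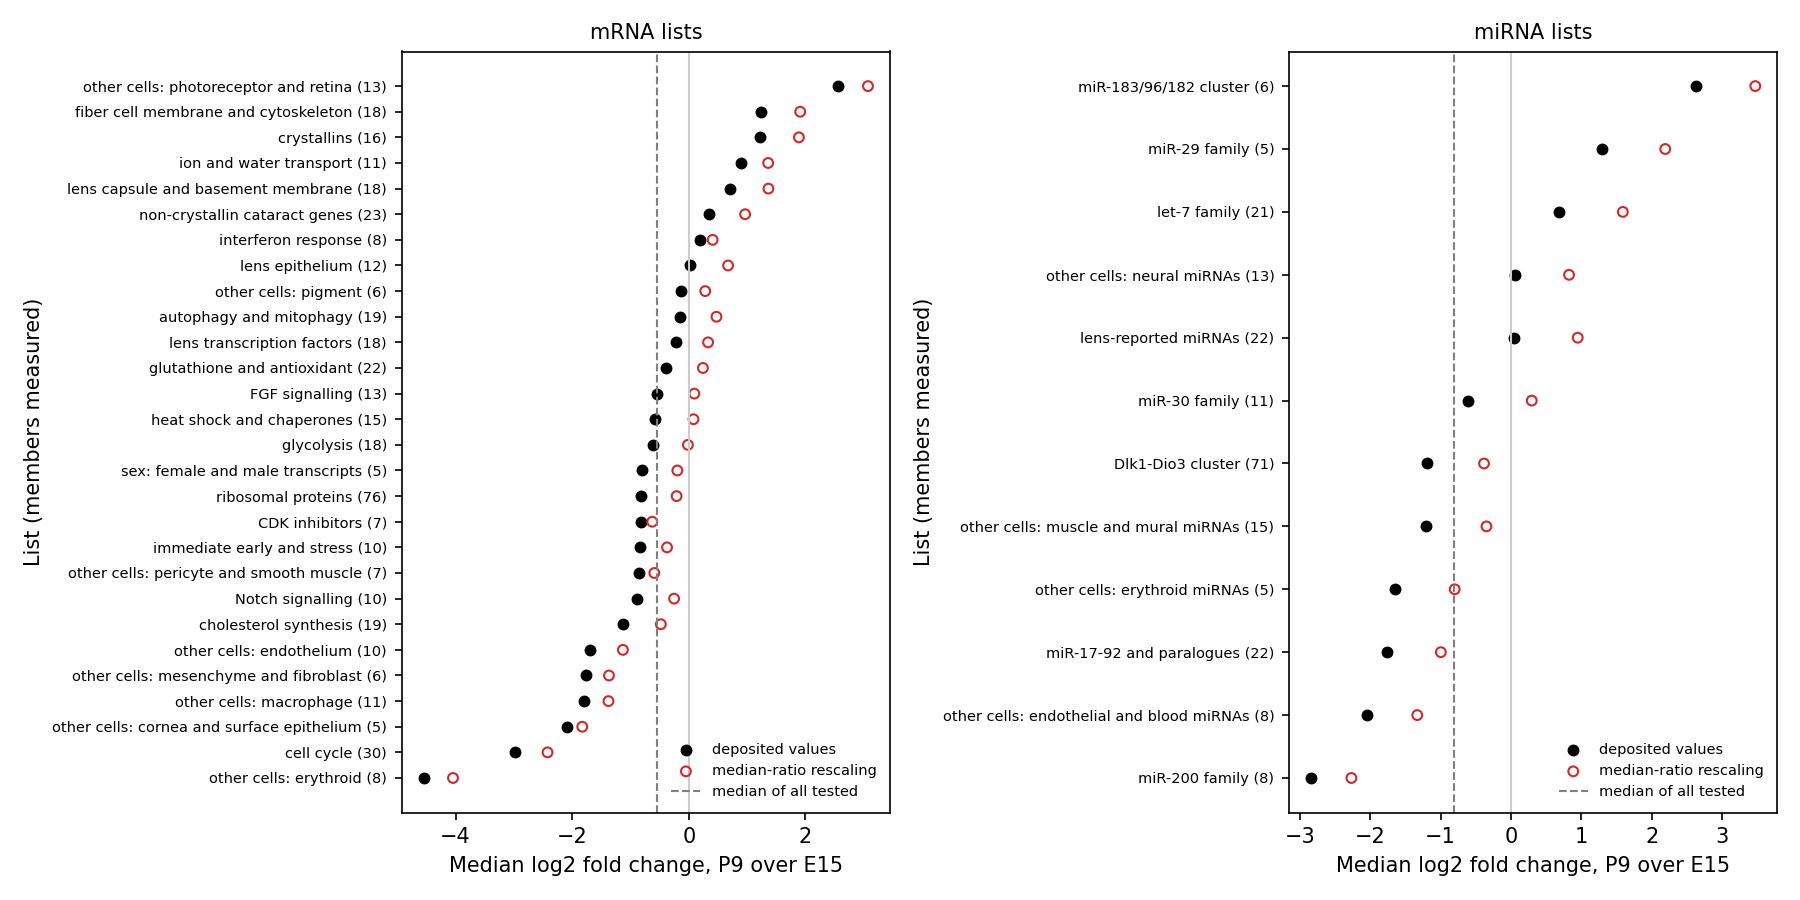
Median log2 fold change (P9 over E15) of each gene and miRNA list; black points are deposited values, red open points median-ratio rescaling, and dashed lines the median of all tested features. Crystallins (1.22 and 1.89) and the cell cycle (-2.97 and -2.42) keep their direction on both scales, while transcription factors, autophagy, antioxidant, FGF, heat shock, pigment and the miR-30 family change sign.

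Among miRNAs, let-7 and the sensory-organ miR-183 cluster (miR-182, miR-183 and miR-96) rose from E15 to P9. All 6 cluster members rose (median 2.63, 3.43 above the median of all miRNAs): miR-96-5p from 52.7 ± 9.61 to 712 ± 290 signal (3.68 ± 0.33), miR-182-5p (chromosome 6, 30165962-30165986) from 11287 ± 3050 to 120607 ± 48404 (3.38 ± 0.26; adjusted p = 2.5e-07) and miR-183-5p from 1382 ± 393 to 9229.96 ± 3004. Of 21 let-7 members 11 rose, 1 fell and 9 did not pass, and 18 rose after median-ratio rescaling; let-7b-5p (chromosome 15, 85707325-85707346) rose from 57.6 ± 20.1 to 299 ± 30.3 (2.40 ± 0.25). In the miR-29 family, which targets collagen transcripts, 4 of 5 rose and 1 did not pass, miR-29b-3p by 3.38 and miR-29a-3p by 1.25. Lens-reported miRNAs rose in 6 of 22, fell in 4 and did not pass in 12 (13 rose and 2 fell after median-ratio rescaling), with miR-31-3p up from 110.5 ± 43.3 to 835 ± 172 and miR-211-5p down from 3361 ± 722 to 886 ± 11.7.

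Epithelial and growth-linked miRNAs fell. All 8 members of the miR-200 family, which maintains epithelial identity, fell (median -2.84): miR-200b-3p from 375 ± 48.4 to 6.16 ± 0.573 (-5.71 ± 0.34) and miR-429-3p by 4.79. The surface-epithelium miR-205-5p fell from 1094 ± 146 to 19.3 ± 0.566 (-5.75 ± 0.23), beside the fall of Krt5 and Krt15. In miR-17-92 and paralogues 18 of 22 fell and 4 did not pass (13 fell and 1 rose after median-ratio rescaling), miR-92a-1-5p by 3.57 and miR-20b-5p by 3.24. The imprinted Dlk1-Dio3 cluster had 50 of 71 falling, 2 rising and 19 not passing (23 and 5 after median-ratio rescaling), with miR-433-3p (213 ± 34.5 to 25.6 ± 0.834) and miR-431-5p (-2.81). Of 11 miR-30 members 7 fell and 4 did not pass (median -0.61), but 0 fell and 3 rose after median-ratio rescaling (median 0.29). Largest among the rest were the falls of miR-216b-5p (294 ± 113 to 3.08 ± 1.35; -6.16 ± 0.32) and miR-217-5p (-4.98) and the rise of miR-193b-3p (42.5 ± 11.6 to 538 ± 156).

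MiRNAs of other cells mostly fell. All 8 endothelial and blood miRNAs fell, miR-142-5p from 312 ± 56.3 to 35.2 ± 10.7 and miR-223-3p by 2.97, beside the macrophage genes. Muscle and mural miRNAs fell in 9 of 15, rose in 3 and did not pass in 3 (4 and 4 after median-ratio rescaling), miR-199a-3p from 2097 ± 619 to 76.2 ± 1.48. Of 5 erythroid miRNAs 3 fell (miR-144-5p -3.18, miR-451a -2.53), miR-486-3p rose by 1.36 and 1 did not pass. Neural miRNAs rose in 2 of 13, fell in 3 and did not pass in 8; miR-124-3p rose from 163 ± 26.3 to 656 ± 369 and miR-128-3p fell by 1.81.

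Of 777 miRNAs 476 changed between E15 and P9 (limma), 93 up and 383 down, with a median of -0.80; after median-ratio rescaling 193 rose and 208 fell (median -0.10). Camera set apart 8 lists: upward let-7 (adjusted p = 5.24e-07), the miR-183 cluster (5.24e-07), miR-29 (0.000114) and lens-reported (0.00209); downward miR-17-92 (0.00140), Dlk1-Dio3 (0.00209), miR-200 (0.00425) and endothelial and blood miRNAs (0.0405). None stayed with an estimated correlation, the lowest being 0.128 for the miR-183 cluster (let-7 0.163, miR-200 0.163, Dlk1-Dio3 0.538). Neural (0.140), miR-30 (0.620), muscle and mural (0.620) and erythroid miRNAs (0.788, direction up with a median of -1.65) were not set apart.

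**Figure D4:**
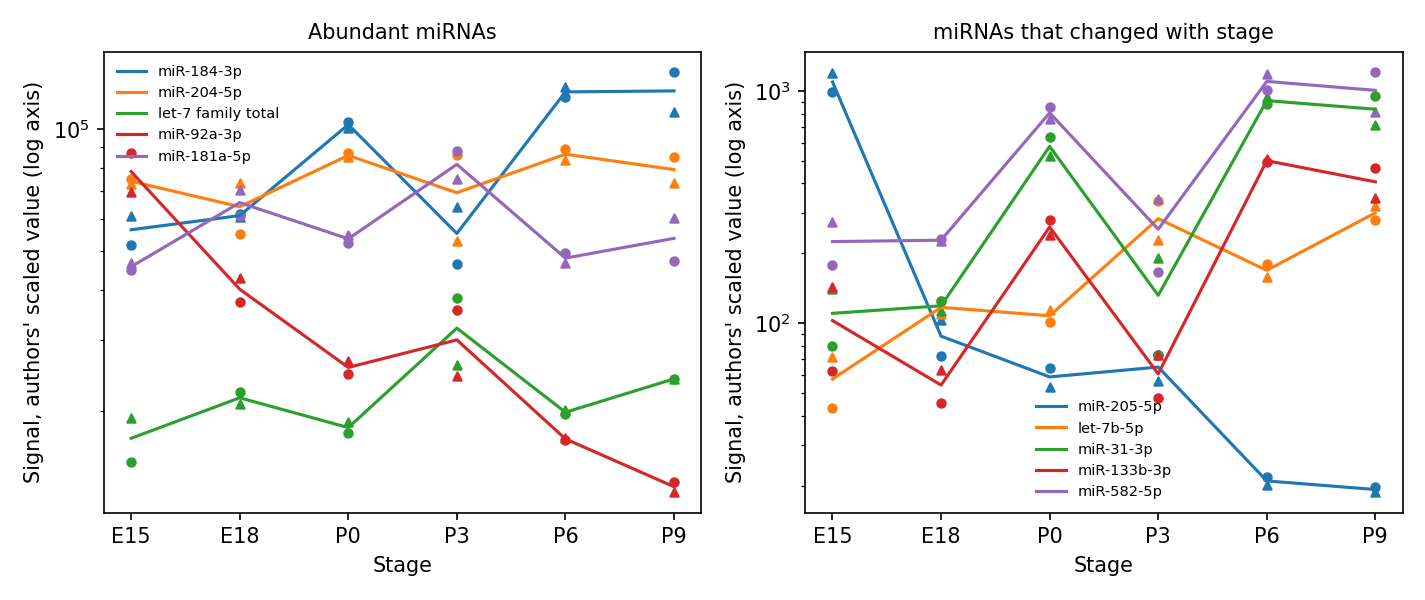
Deposited signal (log scale) of abundant miRNAs (left) and of miRNAs that changed with stage (right), the right panel chosen after the values were seen; circles are replicate A, triangles replicate B, lines the means. MiR-205-5p falls from 1094 at E15 to 19.3 at P9, and miR-31-3p drops from 578 at P0 to 132 at P3 before reaching 909 at P6.

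Taking all postnatal against all embryonic libraries (8 and 4), the lens programme again rose. All 16 crystallins rose, Crybb2 from 74.3 ± 64.0 to 11176 ± 7589 RPKM (7.38 ± 0.06; adjusted p = 1.4e-13), the SDs including the change between stages. Of 18 fiber genes 17 rose and 1 did not pass, Lgsn by 4.18 and Lctl by 3.91, and of 23 cataract genes 16 rose (17 adjusted over the list alone), 3 fell and 4 did not pass, Bfsp1 going from 571 ± 192 to 3115 ± 438. Fewer rose with Rax as a covariate: 7 of the 16 crystallins, 7 of the 18 fiber genes, 2 of the 23 cataract genes, 8 of the 18 capsule genes and 5 of the 11 ion and water genes. Capsule genes rose in 13 of 18 and fell in 4, Col4a4 by 4.10 ± 0.07 and Col4a3 by 4.07 ± 0.07, and ion and water genes rose in 9 of 11 and fell in 1. Hspb1 (2.53 ± 1.92 to 103 ± 58.7), Aldoc (31.5 to 271 ± 82.9), Hmox1 (54.3 ± 35.0 to 420.2 ± 116) and Fgfr3 (33.8 ± 13.4 to 90.5 ± 7.73) rose. In the epithelium 6 of 12 rose and 3 fell (8 and 1 after median-ratio rescaling), and of 18 transcription factors 7 rose and 7 fell (11 and 2), Hsf4 and Prox1 (39.2 ± 15.1 to 78.5 ± 7.10) rising and Meis1, Six3 and Pax6 falling. Pax6 changed by -0.80, and by -0.24 after rescaling. Under the Rax covariate 2 epithelial genes rose and 0 fell, and 2 transcription factors rose and 1 fell.

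All 30 cell cycle genes fell after birth, Ube2c by 2.67, Top2a from 98.0 ± 28.1 to 18.2 ± 9.72 and Mcm5 by 2.45. So did all 19 cholesterol genes (11 after median-ratio rescaling), 15 of 18 glycolytic genes with 2 rising (16 falling adjusted over the list alone, 7 and 3 after rescaling), 71 of 76 ribosomal genes (14, with 7 rising), 7 of 10 Notch genes (5, with 3 rising) and 5 of 7 CDK inhibitors. Hmgcs1, a sterol pathway synthase gene, went from 54.4 ± 11.4 to 21.1 ± 2.67, Ldha from 157 ± 17.9 to 61.1 ± 11.8 and Hes5 from 30.7 ± 12.9 to 5.22 ± 2.93. With Rax as a covariate cell cycle genes fell in 29 of 30, cholesterol genes in 9 of 19, glycolytic genes in 6 of 18 with 1 rising, ribosomal genes in 41 of 76, Notch genes in 1 of 10 with 1 rising and CDK inhibitors in 2 of 7. Autophagy had 7 of 19 rising and 8 falling (11 and 2 after median-ratio rescaling), antioxidant 6 and 11 of 22 (10 and 4), heat shock 4 and 9 of 15 (7 and 4), FGF 3 and 8 of 13 (7 and 4), immediate early 1 and 6 of 10 (2 and 5) and interferon 3 and 1 of 8. Given the Rax covariate autophagy had 4 rising and 3 falling, antioxidant 3 and 8, heat shock 2 and 8, FGF 3 and 1, immediate early 0 and 0 and interferon 2 and 0. Fgf15 (223 ± 107 to 8.65 ± 8.81) and H19 (674 ± 467 to 72.5 ± 80.7) fell, as did the retinal factor Rax (53.4 ± 23.6 to 11.1 ± 4.25). After birth the courses parted: Fgf15 went from 19.8 ± 8.39 at P0 to 1.42 ± 0.125 at P9, while Rax stood at 10.6 ± 1.63 and 9.64 ± 3.06.

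Other-cell markers were mostly lower after birth. All 8 erythroid, all 11 macrophage and all 5 corneal genes fell, as did 9 of 10 endothelial, 6 of 7 pericyte (1 rose) and 4 of 6 mesenchymal genes, among them C1qc (15.2 ± 5.97 to 3.54 ± 3.20), Emcn (-1.66), Krt15 (-1.73) and Col1a1 (-1.40). Most of these calls were lost with Rax as a covariate: all 8 erythroid genes fell, but 3 of 11 macrophage, 2 of 5 corneal, 4 of 10 endothelial, 2 of 7 pericyte and 0 of 6 mesenchymal genes. In that fit all 11 macrophage (median -0.91), 5 corneal (-1.12), 10 endothelial (-1.04) and 6 mesenchymal genes (-1.08) and 6 of 7 pericyte genes (-0.52) were still lower. The median standard error of all genes rose from 0.112 to 0.214, so the lost calls do not show that retinal tissue gave the falls. Retinal genes rose in 7 of 13 and fell in 4, Sag rising by 2.75 and the ganglion cell gene Pou4f2 falling by 2.55, while pigment genes rose in 1 of 6 and fell in 4 on the deposited scale but rose in 2 and fell in 1 after rescaling. Of 5 sex-chromosome transcripts 2 fell. The count was 11172 of 14405 genes (limma), 1470 up and 9702 down, with a median of -0.47, and 3900 up and 3974 down after median-ratio rescaling.

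The miRNA signal after birth against before showed 459 of 777 changed (limma), 98 up and 361 down (196 and 224 after median-ratio rescaling). Let-7 rose in 12 of 21 (17 after rescaling), let-7b-5p by 1.27, and the miR-183 cluster in 4 of 6 (5 adjusted over the list alone), miR-182-5p from 21368 ± 11782 to 64650.0 ± 45554. MiR-29 rose in 4 of 5 (miR-29a-3p 24.5 ± 1.40 to 57.5 ± 9.30) and lens-reported miRNAs in 10 of 22 with 3 falling; miR-375-3p rose from 495 ± 68.1 to 1545 ± 489. All 8 miR-200 members fell, miR-200b-3p by 3.21, as did 16 of 22 in miR-17-92 (17 adjusted over the list alone; miR-18a-3p -2.02), 44 of 71 in Dlk1-Dio3 with 2 rising (23 and 7 after rescaling), and 6 of 11 miR-30 members, of which 0 fell and 2 rose after rescaling. Endothelial and blood miRNAs fell in 7 of 8 (miR-142-5p -1.95), erythroid in 3 of 5 with 1 rising, neural in 4 of 13 and muscle and mural in 9 of 15 with 3 rising (4 adjusted over the list alone). The largest falls were miR-216b-5p (223 ± 106 to 13.0 ± 11.6; -4.41 ± 0.20) and miR-217-5p (-3.49).

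From E15 to E18 single fiber genes and the pigment genes rose, and most erythroid and corneal genes fell. Crybb2 rose by 2.71 ± 0.10 (adjusted p = 1.7e-07), Crygs from 364 ± 164 to 1816 ± 74.5 RPKM, Lctl by 2.16 and Lgsn by 1.99 (3 of 16 crystallins and 5 of 18 fiber genes rose and 1 fiber gene fell, 6 and 4 adjusted over the list alone). The gap junction gene Gja1 rose from 53.9 ± 21.7 to 199 ± 20.6, and Foxe3 fell by 1.84 ± 0.27; in the epithelium 1 of 12 rose and 5 fell (3 and 5 adjusted over the list alone, 1 and 2 after median-ratio rescaling). All 6 pigment genes rose (5 after median-ratio rescaling), Tyrp1 from 2.34 ± 0.957 to 23.1 ± 2.06 and Dct by 2.40. Erythroid genes fell in 7 of 8 (8 adjusted over the list alone), Hbb-y by 7.63 and Hba-x by 4.86, and of 5 corneal genes 4 fell and 1 rose (Krt5 -2.65, Krt15 -2.06). Of 11 transport genes 4 rose, Aqp1 by 2.13. Outside the lists the prostaglandin synthase gene Ptgds (0.856 ± 0.410 to 78.0 ± 11.8; 5.42 ± 0.19) and Tac1 (4.05) rose, while the calpain gene Capn3 (2193 ± 986 to 599 ± 67.8) and H19 (-1.79) fell. None of the 30 cell cycle genes (limma; also 0 adjusted over the list alone), 19 cholesterol genes or 10 Notch genes passed; Top2a measured 103 and 93.2. Given Rax as a covariate 25 of the cell cycle genes did not pass and 5 fell. In the same fit 5 of 11 macrophage, 3 of 7 pericyte and 2 of 10 endothelial genes rose and 0 fell.

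In that pair the balance of rises and falls depended on the setting. Of the calls 37.5% were up under the strict filter (297 up and 496 down, median -0.06) and 74.2% on the non-crystallin scale. At the filter of at least 1 in at least 2 libraries 1318 genes changed (limma), 789 up and 529 down (59.9% up), with a median of 0.05. The count depended on single libraries: it was 5083 without E15 A, 292 without E18 A and 168 without E18 B, and 36 of 67 named calls were lost without some library. The genes named here were not among them, but the list counts include such calls. Among the lists camera set apart were pigment (adjusted p = 1.49e-08), erythroid (1.01e-15), corneal (0.000105), ribosomal (2.68e-09, 6 of 76 falling and 11 adjusted over the list alone) and cataract genes (0.00151), and none stayed with an estimated correlation (0.0529 for pigment and erythroid, 0.0897 for corneal genes). Among miRNAs all 8 of the miR-200 family fell, miR-200b-3p from 375 ± 48.4 to 29.7 ± 9.04, with miR-205-5p (1094 ± 146 to 88.1 ± 22.03) and miR-199a-3p (-2.62). Let-7 rose in 4 of 21 (7 adjusted over the list alone, 9 after median-ratio rescaling), each of the 4 not called without E15 A, E18 A or E18 B, and miR-182-5p rose from 11287 ± 3050 to 31448 ± 845. MiR-200 and the lens-reported list stayed apart with an estimated correlation (adjusted p = 0.0466 each). In all 94 of 777 miRNAs changed, 17 up and 77 down, and 38 up and 39 down after median-ratio rescaling; the count was 51 without E15 A, 57 without E15 B, 27 without E18 A, 42 without E18 B and 161 without P3 A or P3 B, and 19 of 30 named calls were lost without some library.

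Among mRNAs more genes changed at birth than between the other consecutive stages, except with Rax as a covariate. Between E18 and P0 15 of 16 crystallins (16 adjusted over the list alone) and all 18 fiber genes rose: Crybb2 from 129.6 ± 6.37 to 2467 ± 10.1 RPKM (4.24 ± 0.10; adjusted p = 6.2e-09), Crybb1 from 8537 ± 1399 to 23302 ± 1151, Bfsp1 from 592 ± 87.1 to 2624 ± 248 and the lens connexin Gja3 from 97.8 ± 14.3 to 377 ± 0.199. Among transcription factors Pitx3 (10.5 ± 1.80 to 39.2 ± 0.752), Hsf4 (42.1 ± 0.327 to 149 ± 12.3) and Prox1 (1.49) rose, with 7 of 18 rising and 5 falling in the list (8 and 6 adjusted over the list alone, 9 and 2 after median-ratio rescaling). Mip rose from 1462 ± 29.6 to 3356 ± 301, Fgfr3 from 26.6 ± 1.04 to 97.3 ± 12.9, and 12 of 18 capsule genes rose and 4 fell. All 30 cell cycle genes fell, Rrm2 from 36.0 ± 1.48 to 6.63 ± 0.889 and Mcm5 by 2.23, while the CDK inhibitor Cdkn1c rose from 195 ± 11.8 to 379.98 ± 11.9. The Notch targets Hes5 (37.1 ± 3.48 to 4.497 ± 0.475) and Hes1 (-2.19) fell, as did the retinal factors Otx2 (42.7 ± 0.765 to 6.20 ± 2.24) and Rax (58.8 ± 3.79 to 10.6 ± 1.63).

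Markers of other cells dropped in the same interval. Macrophage genes fell in 11 of 11 (Csf1r 16.6 ± 3.27 to 2.54 ± 1.12), endothelial genes in 9 of 10 (Kdr -1.91), pericyte genes in 6 of 7 and erythroid genes in 4 of 8 (Hba-a2 -4.26, Hbb-b1 -4.21). Cholesterol genes fell in 14 of 19 (15 adjusted over the list alone, 7 after median-ratio rescaling), Hmgcs1 by 1.29, glycolytic genes in 11 of 18 with 1 rising (5 and 3), Ldha from 171 ± 12.3 to 58.5 ± 20.9, and ribosomal genes in 22 of 76 with 0 rising (8 adjusted over the list alone), but 0 fell and 4 rose after rescaling. In all 7603 genes changed (limma), 1112 up and 6491 down with a median of -0.41, and 2588 up and 2463 down after median-ratio rescaling; without E18 A the count was 4741, without E18 B 3830 and without P0 B 4760. With Rax, which fell in the same interval, as a covariate 42 genes were called, against 1950 from E15 to E18, and 15 of the 16 crystallins, 17 of the 18 fiber genes, 29 of the 30 cell cycle genes and all macrophage, endothelial, pericyte, cholesterol, glycolytic, ribosomal and Notch genes did not pass. In that fit all 30 cell cycle (median -0.84), 11 macrophage (-0.85), 10 endothelial (-0.84) and 7 pericyte genes (-0.53) were still lower, against 5 of 10 Notch genes. The median standard error of all genes rose from 0.182 to 0.264, so the lost calls do not show that retinal tissue gave the changes. Fiber (adjusted p = 2.43e-22), crystallins (7.33e-19), capsule (2.44e-11) and cell cycle (8.49e-10) were set apart by camera; with an estimated correlation they were not (0.104, 0.127, 0.0631 and 0.445). Of 91 named calls 16 were lost without some library and 17 after median-ratio rescaling.

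Among small RNAs the miR-183 cluster and neural miRNAs fell at birth. The miR-183 cluster fell in 5 of 6, miR-182-5p from 31448 ± 845 to 10602 ± 1980 and miR-183-5p from 3432 ± 515 to 1079 ± 261, and neural miRNAs fell in 5 of 13, miR-9-5p from 5008 ± 198 to 1109 ± 292 and miR-124-3p by 1.79, beside the fall of Otx2 and Rax. MiR-31-3p (119 ± 8.23 to 578 ± 76.1) and miR-133b-3p (54.3 ± 12.2 to 259.9 ± 27.4) rose, the miR-29 family rose in 4 of 5, each of the 4 not called without P0 A or P0 B, and miR-216b-5p fell by 3.13. Camera gave adjusted p = 0.00028 for the cluster and 0.000835 for the neural list (0.285 and 0.305 with an estimated correlation). There were 141 calls (limma), 59 up and 82 down (41.8% up; 52.4% after quantile normalization), against 59, 57, 27 and 44 without E18 A, E18 B, P0 A and P0 B. Of 40 named calls 28 were lost without some library, among them miR-96-5p of the cluster (without E18 A or P0 B).

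From P0 to P3 few mRNAs were called, and several of them turned back later. Crybb2 rose by 1.51 ± 0.10 (2467 ± 10.1 to 7040.19 ± 39.2 RPKM; adjusted p = 7.2e-05), Col4a3 from 6.93 ± 0.559 to 22.5 ± 0.0742, Col4a4 by 1.16 and Srd5a2 from 1.51 ± 0.564 to 19.4 ± 1.13. The stress-response gene Nupr1 fell from 1103 ± 38.0 to 207 ± 5.94 (-2.41 ± 0.23), and the ribosomal Rpl35a (6.40 ± 0.736 to 1.503 ± 0.0453) and spliceosomal Snrpf (-1.55) fell. Ribosomal genes fell in 3 of 76, Rpl38 and Rps19 not called without any 1 of the P0 and P3 libraries (18 adjusted over the list alone; camera adjusted p = 2.25e-20, 0.308 with an estimated correlation). Erythroid genes rose in 3 of 8, each not called without P3 A, Hba-a2 by 2.76 (adjusted p 0.0818 without P3 A, 0.0632 without P3 B), and 1 of 13 retinal genes, Sag, rose by 2.43 (0.176 without P0 A, 0.188 without P0 B, 0.0557 without P3 A, 0.214 without P3 B). All told 75 genes changed (limma; 1554 at an unadjusted p under 0.05), 51 up and 24 down, and 56 after median-ratio rescaling. The count was 315 without E15 A and 303 without E15 B, and 49 without E18 A or E18 B. It was 40, 23, 26 and 24 without P0 A, P0 B, P3 A and P3 B and 47 without P6 A or P6 B, and 14 of 21 named calls were lost without some library.

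MiRNAs changed more widely at P3, where the pools differed most. The miR-183 cluster rose in 5 of 6 (6 adjusted over the list alone), miR-182-5p from 10602 ± 1980 to 62119 ± 5014 and miR-183-5p from 1079 ± 261 to 4814 ± 1200, and neural miRNAs in 5 of 13 (5 and 1 falling adjusted over the list alone), miR-9-5p from 1109 ± 292 to 4505 ± 601 and miR-124-3p by 1.90. Let-7 members rose in 7 of 21 and fell in 1 (9 and 0 after median-ratio rescaling). Let-7b-5p, let-7c-5p, let-7d-5p and let-7g-3p, the 4 with the largest change, were not called without P0 A. Dlk1-Dio3 miRNAs fell in 29 of 71 (31 adjusted over the list alone, 13 after rescaling), miR-495-3p by 1.85, and miR-31-3p (578 ± 76.1 to 132 ± 83.9), miR-133b-3p (-2.11) and miR-345-5p (-2.20) fell. Camera adjusted p was 3.53e-10 for the cluster and 1.72e-05 for Dlk1-Dio3 (0.160 and 0.517 with an estimated correlation). Of 163 called miRNAs (limma) 31 rose and 132 fell, and 55 and 48 after median-ratio rescaling; 21, 61, 92 and 292 were called without P0 A, P0 B, P3 A and P3 B, and 22 of 33 named calls were lost without some library.

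Between P3 and P6 blood-cell and pigment transcripts fell. Hba-a2 went from 445 ± 40.5 to 47.2 ± 3.61 RPKM, Hbb-b1 fell by 2.96, and Pmel went from 33.9 ± 6.74 to 7.02 ± 0.761, with 5 of 6 pigment genes falling (6 adjusted over the list alone; camera adjusted p = 2.12e-09, 0.0882 with an estimated correlation). Dct, Mlana and Tyrp1 were not called without P3 B or P6 B. Macrophage genes fell in 8 of 11 (11 adjusted over the list alone; 2.93e-12 and 0.325), C1qc from 7.63 ± 0.323 to 0.917, not called without P3 A (0.127), P3 B (0.119) or P6 B (0.193), like C1qa, Mrc1 and Csf1r. With Rax as a covariate 2 of the 11 macrophage genes fell, though all 11 were lower (median -1.47), and 5 of 6 pigment genes fell. Crybb2 rose to 14018 ± 107 (0.99 ± 0.10), Nupr1 returned from 207 ± 5.94 to 1547 ± 6.50 (2.89 ± 0.23) and Rpl35a rose by 1.27. Of 30 cell cycle genes 2 fell, Ube2c and Birc5, neither called when any 1 of the 10 libraries after E15 was left out. In the list 29 fell when adjusted over the list alone (median -0.91; 2.3e-13 and 0.325). In total 155 genes changed (limma), 31 up and 124 down (20.0% up; 40.7% up after median-ratio rescaling) with a median of -0.21. Leaving out E15 A or E15 B gave 2224 and 2221, E18 A or E18 B 79 and 82, and P3 A, P3 B, P6 A and P6 B gave 28, 27, 54 and 18. Of 27 named calls 20 were lost without some library.

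The same interval reversed several miRNAs. MiR-31-3p rose from 132 ± 83.9 to 909 ± 44.6, miR-133b-3p from 60.6 ± 18.1 to 502 ± 8.54, miR-193b-3p by 2.82 and miR-24-3p by 1.36, and miR-29 rose in 2 of 5 (3 adjusted over the list alone). Endothelial and blood miRNAs fell in 5 of 8 with miR-142-5p (235 ± 51.0 to 55.3 ± 20.5) beside the macrophage genes, let-7 fell in 5 of 21 and rose in 1 (7 and 1 adjusted over the list alone; let-7i-5p -0.92), and miR-1247-5p fell by 3.01. Altogether 197 of 777 changed (limma), 95 up and 102 down, against 327 without P3 B, 128 without P6 A and 89 without P6 B, and 19 of 39 named calls were lost without some library.

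From P6 to P9 photoreceptor transcripts and a few lens genes rose. Lgsn went from 52.4 ± 3.22 to 300.2 ± 113 RPKM (2.44 ± 0.22; adjusted p = 0.0039, and 0.0733 without P6 B). Of 13 retinal genes 3 rose, Sag from 10.2 ± 2.96 to 70.8 ± 42.0 (2.57) and Pde6b among them (7 adjusted over the list alone, 6 after median-ratio rescaling; camera adjusted p = 5.17e-19, 0.211 with an estimated correlation). Of 11 transport genes 2 rose, Aqp5 among them, and H19 fell from 18.7 to 6.37. Sag, Pde6b, Aqp5 and H19 were each not called when any 1 of 9 or 10 libraries was left out, all except those of E15 and at most 1 more (without P6 B 0.640, 0.586, 0.586 and 0.361). None of the 30 cell cycle genes passed (limma; also 0 adjusted over the list alone), although the list lay low (median -0.53; 1.09e-14, 0.763 with an estimated correlation). Few genes were called: 16 (limma, with 767 at an unadjusted p under 0.05), 11 up and 5 down, and 42 after median-ratio rescaling (32 and 10). A pseudocount of 0.1 gave 3 up and 7 down, and the strict filter 2 and 2. All 5 named calls were lost without some library, the counts being 0 without P6 B, 7 without P9 B, 27 without P9 A, 49 without E15 A or E15 B, 4 without E18 A or E18 B, and 6 without any of P0 A, P0 B, P3 A, P3 B or P6 A. No miRNA was called (limma; 0 of 777, 75 at an unadjusted p under 0.05, also 0 after either rescaling); the miR-183 cluster had a median of 0.58 and camera adjusted p = 2.66e-07 (0.325 with an estimated correlation).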

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

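Tests chosen only after the data were seen are the non-crystallin scale, the retina marker covariate (1 degree of freedom, confounded with stage), the fits without P3 and the lists without each library. The other settings were fixed beforehand. Most named values were picked because they were called and changed most, so keeping their call and direction is partly built in. Direction was kept in nearly all of the 751 named values. The call was the same in 706 without trend, 721 with a pseudocount of 0.1 and 675 without a filter (76 weaker). It was the same in 661 after quantile normalization (76 weaker, 1 stronger, 13 uncalled ones changing sign). Median-ratio rescaling kept 662 (72 weaker, 2 reversed, 15 uncalled ones changing sign), and the strict filter 628 of 633. The retina marker covariate changed more: of 479 named mRNA values 315 kept their call, 142 were weaker, 8 reversed and 14 uncalled ones changed sign. With each library left out, 8198 of 8970 named values kept their call, 714 were weaker, 13 stronger and 0 reversed; where this leaves a stage with 1 library, that lone pool is assumed to vary like the others. Leaving out a library also turned the sign of 45 values that were uncalled in the full fit. A count-based normalization was not run, since the tables hold no counts, and a fit with only the libraries compared does not apply to postnatal against embryonic, which uses all of them. Depth limits low values: 1 RPKM of a 2 kb transcript is 40.8 to 88.0 reads, and the depth of the small-RNA libraries is unknown. Unless a setting by its construction removes genes, libraries or smaller changes, the cause of each difference was not tested.

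Scaling moved many of the mRNA counts. Across the 6 stages the count was 6847 after median-ratio rescaling, 7040 after quantile normalization and 6765 on the non-crystallin scale, against 10687. For P9 against E15 it was 5897, 6144 and 5938 against 9229. For P0 against E18 it was 5051 after median-ratio rescaling and 5053 on the non-crystallin scale against 7603, and for P9 against P6 42, 48 and 38 against 16. For miRNAs, P3 against P0 gave 103 after median-ratio rescaling and 90 after quantile normalization against 163.

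The strict filter, which tests fewer genes, gave 5284 genes across stages, 4784 for P9 against E15, 5249 for postnatal against embryonic, and 793, 3697, 49, 91 and 4 for the consecutive pairs in order. Requiring an absolute log2 fold change of at least 1, which removes smaller changes, gave 5603 across stages, 3478 for P9 against E15, 2182 for postnatal against embryonic, 506 for E18 against E15, 2260 for P0 against E18 and 46 for P3 against P0. For miRNAs the same requirement gave 221 for postnatal against embryonic, 86 for P0 against E18 and 104 for P3 against P0. No filter gave 89 miRNAs for P0 against E18 and 100 for P3 against P0. A pseudocount of 0.1 gave 10 genes for P9 against P6 and 62 miRNAs for E18 against E15. With a detection level of 10 the mean was 4802.75 genes and 426.75 miRNAs per library.

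Using only the libraries of the 2 stages, which leaves fewer residual degrees of freedom, gave 5558 genes for P9 against E15, 4 for E18 against E15, 30 for P3 against P0, 249 for P6 against P3 and 0 for P9 against P6, and 46, 23 and 33 miRNAs for E18 against E15, P3 against P0 and P6 against P3. Without P3 there were 7 genes for P9 against P6 and 161 miRNAs for E18 against E15. The retina marker covariate gave 5221 genes across stages, 5226 for P9 against E15, 2521 for postnatal against embryonic, and 1950, 42, 157, 80 and 45 for the consecutive pairs in order. With an estimated correlation 1 gene list and 0 miRNA lists were set apart between E15 and P9, against 16 and 8.

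Replicate letters share only a name: over 15 pairs of stages, deviations of libraries with the same letter correlated by -0.25 to 0.21 for mRNA and -0.23 to 0.08 for miRNA. As a replicate block they gave 10341 genes across stages, 9073 for P9 against E15, 11112 for postnatal against embryonic, 1048, 7436, 57, 104 and 9 for the consecutive pairs, and 484, 470, 460, 84, 117, 148, 191 and 0 miRNAs in the same order.

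Leaving out each library gave 8286 to 11724 genes across stages, 7125 to 10446 for P9 against E15, 9953 to 11687 for postnatal against embryonic, 168 to 5083 for E18 against E15, 3830 to 9165 for P0 against E18, 23 to 315 for P3 against P0, 18 to 2224 for P6 against P3 and 0 to 49 for P9 against P6, with 11 to 17 lists set apart and 12717.8 to 12895.3 genes detected. For miRNAs the ranges were 456 to 605, 391 to 516, 407 to 505, 27 to 161, 27 to 202, 21 to 292, 89 to 327 and 0 to 0 in the same order, with 7 to 8 lists and 655.545 to 666.273 miRNAs detected.

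Few named genes turned direction. Dct, postnatal against embryonic, was at 0.0432 after median-ratio rescaling, 0.0696 on the non-crystallin scale and 0.31 with the retina marker covariate, which also turned Optn (-0.10), Pfkp (0.71) and Notch1 (0.0835) in that comparison and Ldhb (0.0567), Dll1 (0.00315), Hspa1b (0.10) and Hspa1a (0.0695) for P0 against E18. MiR-30d-5p, P9 against E15, was at 0.0851 after median-ratio rescaling.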

Other observations

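Chosen only after the results were seen were the tests of crystallin share, retinal tissue, lens share, pool age, small-RNA scaling, photoreceptor RNA and splits of whole stages, while those of the E15 A omission, of miRNA sites and of drawn splits were written beforehand. The genes named next were chosen after their values were seen. Several RNAs were lower at P3 than at both neighbouring stages. Snrpf went from 13.4 ± 0.291 RPKM at P0 to 3.99 ± 0.901 at P3 and 11.8 ± 1.39 at P6, beside Nupr1 (1103, 207 and 1547), and miR-582-5p from 805 ± 70.3 to 254 ± 123 and 1100.1 ± 120.4. Capn3 measured 2193 ± 986 at E15, 807 ± 48.5 at P0 and 247.7 ± 1.17 at P9, and the galectin-related gene Grifin 439 ± 203, 963 ± 2.89 and 1826 ± 37.7. MiR-126b-3p differed between the E18 pools (37995 in A, 14324 in B), while miR-126a-5p stood at 12714 and 11129. Gapdh, usually abundant, was deposited at 11.1 RPKM at E15, a gene whose copies share reads.

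Most mRNAs called between E15 and P9 were lower at P9 (7983 of 9229). Retinal tissue in E15 A is argued against as the whole cause, since 6625 genes were still called lower without that library. Retinal tissue over all libraries stays open as part of it. With Rax as a covariate 3931 genes were called lower and 1295 higher, and the median was -0.28, but that fit cannot decide it. Rax is confounded with stage and did not follow photoreceptor genes after birth. From P0 to P9 it went from 10.6 to 9.64 RPKM while Sag went from 0.169 to 70.8. A growing crystallin share could account for part of it. The non-crystallin share of RPKM changed by -0.78 in log2 (67.0% to 39.0%), the median gene by -0.54, and by -0.64 among genes passing the strict filter. Summed RPKM meanwhile rose from 473314 ± 48844 at E15 to 629272 ± 10390 at P9, so non-crystallin RPKM fell by less than its share did. The share is thus not on the scale of the medians and cannot show how much of the shift it covers. Nor can it separate a share effect from a fall of total mRNA per cell, and age, which the design names, stays open and untested. Cell cycle genes, all 30 lower after rescaling too, go beyond that shift.

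Retinal markers were higher in E15 A than in E15 B. All 6 measurable members of the list were, by a median log2 ratio of 1.62 (SD 0.261 over members, 1.35 to 1.95), as more retinal tissue carried along with the lenses might give. A smaller lens share alone is argued against, because it would raise every other cell type alike: erythroid markers differed by 0.22 (SD 0.168) and mesenchymal ones by 0.01 (SD 0.246), and the highest member of any other list of non-lens cell markers (1.27, macrophage) stayed below the lowest retinal one. A smaller lens share beside the retinal tissue stays open, since crystallins (-0.73) and fiber genes (-0.92) were lower in E15 A and macrophage (0.71), pigment (0.43) and endothelial markers (0.40) higher. A difference in age stays open too: the embryonic globins, which fall towards E18, were higher in E15 A, with log2 ratios that are -0.545% (Hbb-y), -9.03% (Hba-x) and -12.5% (Hbb-bh1, under 4 RPKM) of the distance of the same gene from E15 B to E18. Beyond age no biological explanation was tested, since both pools carry the same labels.

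The miR-183 cluster, abundant in photoreceptors, was higher at P9 than at E15. Scaling of the small-RNA values is argued against, since the median log2 fold change was 3.47 after median-ratio rescaling. RNA of photoreceptors in the lens libraries stays open and could carry the rise: over the 6 stages the A to B log2 ratios of retinal mRNAs and of the cluster correlated (Pearson r = 0.89, exact permutation p = 0.0167, adjusted p = 0.0181; Spearman rho = 0.829, exact p = 0.0583), and r was 0.705 without E15 and P9, the 2 farthest. As high an r was found for 9 of 777 miRNAs, and for miR-124 and miR-9 r was 0.888 (exact permutation p = 0.0181; rho = 0.714, exact p = 0.136; r = 0.679 without the same stages). Expression in the lens itself stays open, and age with it, untested.

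A hypothesis of this re-analysis was that miRNA families that rose lower the mRNAs bearing their sites, and that those that fell release theirs. Among 12357 genes with a 3' UTR (85.8% of those tested), genes with a site were compared with genes without in 10 strata of UTR length, by 100000 permutations, and against 200 shuffled sites. Of 5 rising families 1 passed both: let-7b (-0.06, permutation p = 0.00037, adjusted p = 0.00185, stronger than 100% of shuffled sites), while miR-182, miR-96, miR-183 and miR-29a did not. Let-7b-5p was a small part of its family: it went from 57.6 ± 20.1 to 299 ± 30.3 signal between E15 and P9. The let-7 total went from 17143 ± 3011 to 24051 ± 4.57, so the family rose far less than let-7b-5p. Of 5 falling families 2 passed: miR-92a (0.09, permutation p = 1e-05, the smallest possible, 99.5%) and miR-17 (0.05, permutation p = 0.00359, adjusted p = 0.0120, 96.5%), while miR-200b, miR-205 and miR-199a did not. As a general rule the hypothesis was thus not borne out in either direction (1 and 2 of 5), and the shifts that passed are small. The families that did not pass cannot argue against targeting, because the size of shift the test could detect was not measured. MiR-182, miR-96 and miR-183 also belong to 1 cluster, whose rise may lie in photoreceptor RNA. Matching 950 genes through older symbols was added after a first run on 11418 genes (79.3%) was seen; in that run miR-17 stood at 95% and did not pass, so its result depends on the addition.

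The counts of calls after against before birth were set against other splits of the libraries. Among 100 splits of the 12 libraries into 8 and 4, drawn from 495 and including the real one, only 1, the real split, gave as many calls (11172 mRNAs, with 3329 the highest of the others, and 459 miRNAs, with 272). Of these splits 95 part the pools of a stage and so put differences between stages into the residual, so their lower counts are built in and decide nothing. Among the 15 splits of the 6 stages into 4 and 2 that keep stages whole, 1, the real one, gave as many calls, with 10327 mRNAs and 456 miRNAs the highest of the others (P6 and P9 apart); 15 splits are too few for a share under 0.05.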
